A study of Mus musculus with 8 samples.

How the data were processed

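Expression was measured on 8 Agilent 2-colour oligonucleotide arrays of mouse genes, 4 from wild-type (WT) and 4 from knockout (KO) samples. Per the labels, each array carried cRNA made from 0.5 µg of total RNA of 1 sample in Cy5 and the RNA of WT replicate 3 in Cy3, so that 1 reference RNA lay on all arrays and the array of WT replicate 3 was a hybridisation of that RNA with itself. No dye was swapped. A constant dye effect and the reference cancel in the difference between KO and WT, as far as the reference is read alike on every array. WT replicate 3 was counted as 1 WT sample, by its Cy5 channel. The series calls the samples of a group biological replicates and numbers them 1 to 4 in both groups, without giving animals or litters, so the p-values measure the spread between these samples. Per the file headers, the 8 arrays lay on 1 slide, with all KO arrays in one row of the slide and all WT arrays in the other, so slide row and genotype cannot be told apart.

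The deposited scanner files hold intensity values per spot, made by the authors with Agilent Feature Extraction 10.7.3.1 per the submitters' processing notes, and the array annotation in them is for the mouse build mm9. The median Cy5 and Cy3 intensity and the median local background of each of the 62976 spots were used, because the files hold no mean signals, which the design fixed beforehand had named. The files also hold a log10 ratio of Cy5 over Cy3, for which the authors' scanner software subtracted background, removed spatial trends and normalised the dyes, per the file headers. The deposited series value table is on the same log10 scale with Cy5 over Cy3. Its columns followed the scanner ratios with r of at least 0.999999, with a largest difference of 0.00496. Its columns had medians of 0 on 7 arrays and 0.0152 on the array of KO replicate 3, and they were not centred further.

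From the intensities, background was corrected with normexp (offset 50) and log2 ratios of Cy5 to Cy3 were normalised by loess within each array, with control spots at weight 0, in limma 3.58.1 under R 4.3.3, with jsonlite 2.0.0 and version 1.17.8 of data.table. Figures were drawn with matplotlib 3.10.9. Spots that the scanner software marked as non-uniform or population outliers were left out, and the spots of one probe were averaged. A probe was kept if Cy5 was well above background on at least 4 of the 8 arrays, with unflagged values on at least 3 arrays of each group. Systematic names were matched without version to the RefSeq table of the assembly GRCm38.p6. Of 37850 distinct names 21717 matched, and the others kept the name in the files. Where several probes of a gene passed, the one with the highest mean log2 intensity was used. This left 23343 genes or unnamed transcripts, 15116 of them with a gene symbol. No coordinates are printed, because the files and the table use different builds.

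KO and WT were compared with limma's lmFit and eBayes, 2-sided, with Benjamini-Hochberg adjustment over all 23343, a threshold of 0.05, and a second count that also required at least 2-fold. Of 28 gene lists fixed before the data were examined, 27 were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, on genes with values on all arrays. The list of sex-linked genes was not tested as a set. All adjusted p-values below come from limma. The genes named are Dot1l, the 10 largest rises and falls among genes past the threshold whose KO and WT arrays did not overlap (all of them where fewer passed), leaving out clone, accession, Rik and similar provisional names, and from each list up to 4 measured members with the smallest p. This rule takes 113 genes. The text gives values for those of the shifted lists and for a few members of the others. Genes outside the rule are said to be chosen after their values were seen. In simulated data for KO minus WT with 4 arrays against 4 and 23343 genes, limma recovered 95 of 100 genes changed by 1 on the log2 scale and 99 of 100 changed by 2, with 15 false calls. A simulated fall of the S phase list was called with 0 of the other lists. Each simulated gene was drawn independently and no simulated array stood apart. The estimated correlation within the real S phase list was 0.45, so the simulation does not test list calls or recovery under such correlation.

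Alternatives tried were a normexp offset of 0, no background subtraction, the scanner's own log ratio, median centring without loess, the series value table, Cy5 alone with quantile normalisation, scaling between arrays, no filter or a filter on all 8 arrays, an intensity trend with robust hyperparameters, array weights, the mean over all probes of a gene, replicate number as a block, and each array left out in turn. For the lists, camera with an estimated correlation and fry were also run. No array was left out of the comparison itself. The number of arrays limits the precision.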

Results

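Gene expression was profiled in ureteric bud cells from kidneys of newborn C57BL/6 mice (postnatal day 0). The ureteric bud is the epithelial tube that branches to form the collecting ducts, and its cells were collected by flow sorting of GFP-positive cells. The series compared 4 wild-type (WT) samples with 4 samples in which Dot1 had been deleted from Hoxb7-positive cells (KO). Dot1l encodes a methyltransferase of histone H3. Each sample was read on its own array, as a log2 ratio of the sample in Cy5 to the RNA of WT replicate 3 in Cy3. Arrays are named below by group and replicate number. The percentage of spots with Cy5 well above background ranged from 52.4% to 56.2% on the WT arrays, and was 59.1% on KO 1, 68.9% on KO 2, 95.2% on KO 3 and 61.5% on KO 4. Median Cy5 signal was 98.8 ± 6.28 (SD, n = 4) on the WT arrays. It was 122, 137, 636 and 126 on KO 1 to KO 4, so every KO array was brighter than every WT array (exact permutation test, 2-sided, p = 0.0286, the smallest that 4 against 4 allow, n = 4 per group).

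The arrays did not separate fully by group. Over the log ratios of all genes with complete values, the first principal component held 55.8% of the variance. The WT arrays lay between -25.72 and -18.40 on it, and KO 1, KO 3 and KO 4 at 35.72, 24.16 and 50.21. KO 2 lay at -19.89, among the WT arrays. Genes more than 2-fold away from the WT mean numbered 961 on KO 1, 87 on KO 2, 504 on KO 3 and 1107 on KO 4, and between 83 and 146 on each WT array set against the other WT arrays. KO 3 also had 7665 spots marked as non-uniform or outlying by the scanner software, against 175 to 216 on the other arrays.

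The targeted gene did not pass the test between the KO-labelled and the WT arrays. Dot1l (NM_199322) had a mean log2 ratio of -0.02 ± 0.08 (SD, n = 4) in WT and 0.16 ± 0.19 (SD, n = 4) in KO, a log2 difference of 0.18 ± 0.11 (SE; limma adjusted p = 0.342). It was read by 1 probe, and its log2 difference was -0.18 with median centring (adjusted p = 0.615) and 0.34 without KO 2 and KO 3 (adjusted p = 0.0299). Whether that probe lies in the deleted part of the gene is not given in the sources used here, so this value does not check the labels. The groups below are those of the labels.

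Between KO and WT, 2 genes passed the threshold of 0.05, both lower in KO. 1190007I07Rik (NM_001135567), an uncharacterised gene chosen after its values were seen because the naming rule leaves out provisional names, had a log2 ratio of -0.07 ± 0.02 (SD, n = 4) in WT and -1.46 ± 0.13 (SD, n = 4) in KO. Its log2 fold change was -1.38 ± 0.09 (SE; limma adjusted p = 7.52e-04), a 2.61-fold difference. Gadd45gip1 (NM_183358), which encodes a mitochondrial ribosome protein, fell from 0.61 ± 0.06 (SD, n = 4) to -0.33 ± 0.16 (SD, n = 4), a log2 fold change of -0.94 ± 0.10 (SE; limma adjusted p = 0.0410). Both genes were lower on 4 of 4 KO arrays, KO 2 included. The other tested probe of Gadd45gip1 had a log2 difference of 0.05, and 1190007I07Rik has 1 tested probe. No gene rose past the threshold, and 1190007I07Rik alone passed with at least 2-fold. At an unadjusted p under 0.05 there were 5616 genes, or 24.1% of 23343.

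Of the 21215 genes with values on all 8 arrays, KO and WT arrays did not overlap for 2438, 817 higher and 1621 lower in KO. That is 11.5%, where chance gives 2.86% on average over all ways of dividing the arrays. The share was not computed for the other divisions, and genes that vary together can move it far from that average. Slide row and genotype also cannot be told apart, so the excess is no evidence of a genotype effect. The number of genes called depended on KO 2. Without that array limma called 4947 genes, 2335 higher and 2612 lower in KO. Of these, 650 differed by at least 2-fold, 562 higher and 88 lower. These counts rest on the brightest probe of each gene. For 149 of the 562 another probe was tested, with a median change of 0.19 against 1.41 at the probe used. For 31 of the 88 it was -0.12 against -1.12. The other probe reached 2-fold the same way for 22 and 2 genes, so the counts are of probes more than of genes. Without KO 3 limma called 8, 5 higher and 3 lower. Without both KO 2 and KO 3, a comparison chosen after the data were seen, it called 5510, 3149 higher and 2361 lower. Leaving out any other array gave between 1 and 3 genes, and Gadd45gip1 passed without KO 2 but not without any other single array (adjusted p between 0.0520 and 0.161). 1190007I07Rik passed without any one array (highest adjusted p = 0.0102). Among the normalisations tried, it did not pass with Cy5 alone (adjusted p = 0.147) or median centring in place of loess (adjusted p = 0.0649), and over all 22 alternatives its adjusted p ranged from 1.23e-04 to 0.147. Gadd45gip1 passed in 7 of 22, with adjusted p from 4.23e-04 to 0.194. Median centring moved the median log2 fold change of all genes to -0.30 and Cy5 alone to -0.17, and directions under these settings are relative to that shift.

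**Figure D1:**
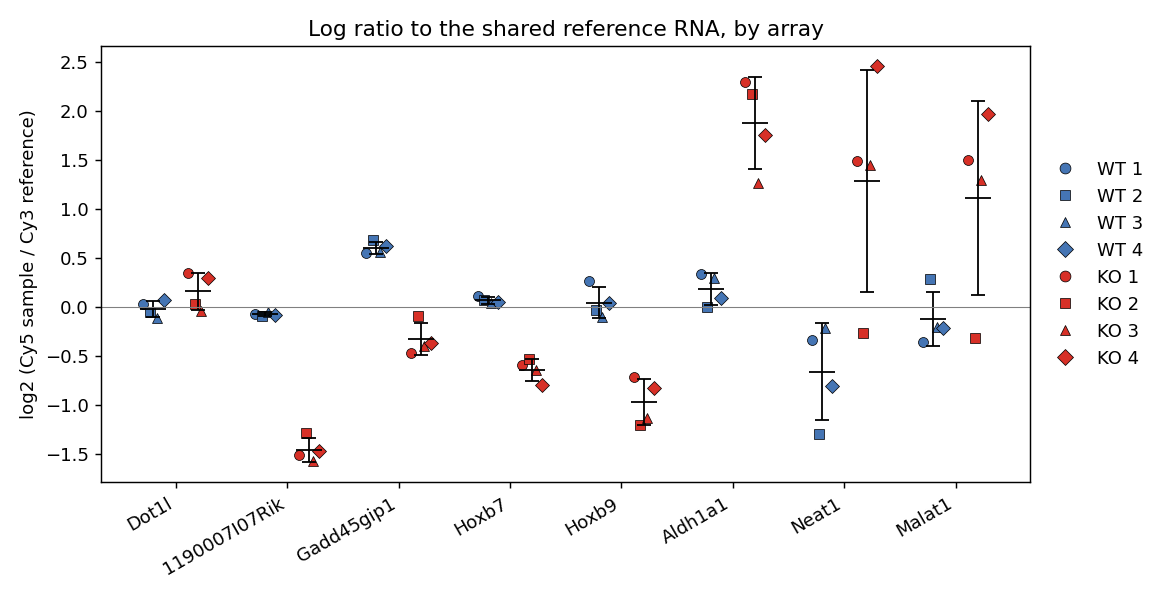
Log2 ratio of Cy5 sample to Cy3 reference on each array for 8 genes, with the mean and SD of each group of 4 as bars; colours mark WT and KO and symbols the replicate number. 1190007I07Rik lies between -1.57 and -1.28 on the KO arrays, whereas Neat1 and Malat1 are high on KO 1, KO 3 and KO 4 and at -0.27 and -0.31 on KO 2.

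Genes of DNA replication were lower in KO as a list. Of 32 measured members of the S phase list, 29 had a negative log2 fold change, with a median of -0.30 (camera adjusted p = 2.32e-05), a call lost with an estimated correlation between genes (adjusted p = 0.992) and with fry (adjusted p = 0.384). By array the list medians of the groups overlapped, with KO 1 at -0.05 and WT 3 at -0.10. Mcm2 and Mcm5, subunits of the replicative helicase, had log2 fold changes of -0.50 ± 0.11 and -0.63 ± 0.15 (SE). Pold1, the catalytic subunit of DNA polymerase delta, had -0.56 ± 0.14, and Rrm1, a subunit of ribonucleotide reductase, -0.42 ± 0.11. All 4 genes were lower on 4 of 4 KO arrays, but they were named for their small p, which favours such separation. No member passed over all genes tested, and 10 were lower when adjusted over the list alone. The shift kept its direction and its camera call in all 22 alternatives that refitted the genes. These included the fits without KO 2 (adjusted p = 0.00566) and without WT 2, where the median was -0.19. The highest camera adjusted p among them was 0.0160. Here and for the lists below, these 22 alternatives kept the preset correlation of 0.01, so they do not test it. With that setting at least 6 lists shifted in 32 of the 35 splits of the arrays into 4 and 4.

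Mitotic genes were lower in KO as a list: the G2 and M phase list had 28 of 35 members below 0 and a median of -0.23 (camera adjusted p = 0.00789), a call lost with an estimated correlation (adjusted p = 0.992). By array the list medians overlapped, with KO 1 at 0.09 and WT 3 at -0.05. Foxm1, a transcription factor of mitotic genes, had a log2 fold change of -0.39 ± 0.11 (SE), and -0.03 at its other tested probe. Cdca3, Bub1b and Ube2c had -0.35 ± 0.10, -0.33 ± 0.10 and -0.41 ± 0.13. No member passed over all genes or adjusted over the list alone. The list passed in 18 of 22 alternatives (adjusted p from 3.34e-05 to 0.128). The call was also lost without WT 4 (median -0.15, adjusted p = 0.128), without KO 2 (adjusted p = 0.0603) and with Cy5 alone (adjusted p = 0.0557).

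Hox and Meis genes, which pattern the body axis and its organs, were lower in KO as a list, with 29 of 36 below 0 and a median of -0.14 (camera adjusted p = 0.0361), a call lost with an estimated correlation (adjusted p = 0.992). By array the list medians overlapped, with WT 4 at -0.24 and KO 3 at -0.18. Hoxb7, the gene whose expression defined the deletion, had a log2 fold change of -0.71 ± 0.08 (SE; limma adjusted p = 0.0570), and Hoxb9 of -1.02 ± 0.13 (adjusted p = 0.0677). Hoxd9 had -0.50 ± 0.10 and Hoxa10 -0.68 ± 0.19. Hoxb7, Hoxb9 and Hoxd9 were lower on 4 of 4 KO arrays, with KO 2 at -0.53 for Hoxb7 and at -1.21 for Hoxb9. Being named for their small p favours such separation. No member passed over all genes and 4 were lower when adjusted over the list alone. The list passed in 12 of 22 alternatives (adjusted p from 7.58e-04 to 0.225). The call was also lost without WT 2, WT 3, KO 2 or KO 4 (adjusted p = 0.0994, 0.0515, 0.225 and 0.0584), and without WT 4 the median was -0.23.

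Genes of the ureteric bud tip, where branching takes place, were lower in KO as a list. Of 20 members 14 had a negative log2 fold change and the median was -0.31 (camera adjusted p = 0.0412), a call lost with an estimated correlation (adjusted p = 0.992). By array the list medians overlapped, with KO 1 at 0.09, KO 2 at 0.04 and WT 3 at -0.02. Slco4c1, an organic anion transporter, had the largest difference among the 4 with the smallest p, at -1.54 ± 0.25 (SE; limma adjusted p = 0.0933). Gfra1, a co-receptor for the branching signal GDNF, had -0.77 ± 0.22, the receptor kinase gene Met -0.54 ± 0.15 and the transcription factor gene Sox8 -0.42 ± 0.10. No member passed over all genes and 5 were lower when adjusted over the list alone. The list passed in 11 of 22 alternatives (adjusted p from 0.00438 to 0.125). The call was also lost without WT 1, WT 2, KO 2, KO 3 or KO 4 (adjusted p = 0.116, 0.0811, 0.0709, 0.0799 and 0.0764).

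The wider list of ureteric bud and collecting duct identity did not shift (median 0.12; camera adjusted p = 0.987), with members on both sides. Its median was 0.03 without KO 2, 0.06 without KO 3, -0.03 with scaling between arrays and -0.40 with median centring. Tfap2a and Pax2, transcription factors of this epithelium, had log2 fold changes of -0.91 ± 0.13 (SE; limma adjusted p = 0.0805) and -0.40 ± 0.09, and the keratin gene Krt18 had 0.79 ± 0.20, or -0.00796 with median centring. A second tested probe of Tfap2a had -0.07. Adjusted over the list alone, 3 members were higher and 7 lower, and none passed over all genes.

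Differentiated collecting duct cells showed no list shift. Principal cell genes had a median of -0.14 (camera adjusted p = 0.987), with Ptger1, a prostaglandin receptor, at -0.62 ± 0.14 (SE), Hsd11b2, which protects the mineralocorticoid receptor from glucocorticoids, at -0.49 ± 0.13, and the kinase gene Sgk1 at 1.16 ± 0.30. Adjusted over the list alone, 3 principal cell genes were higher and 2 lower. Intercalated cell genes had a median of 0.13 (camera adjusted p = 0.199), with Kit at 0.60 ± 0.12 as the 1 member that was higher when adjusted over the list alone. Urothelium genes had a median of 0.27 (camera adjusted p = 0.362), or 0.15 without KO 2, and no member passed either way. With Cy5 alone the urothelium list passed, at 0.23 (camera adjusted p = 0.0286).

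Interferon response genes were higher in KO as a list, with 23 of 25 above 0 and a median of 0.20 (camera adjusted p = 0.00908), a call lost with an estimated correlation (adjusted p = 0.992). Ddx58, a sensor of viral RNA, had a log2 fold change of 0.35 ± 0.11 (SE), but -0.13 at its other tested probe. The oligoadenylate synthase genes Oas1a and Oas2 had 0.86 ± 0.28 (0.41 at the other tested probe) and 0.48 ± 0.17, and Stat2 0.31 ± 0.13. No member passed over all genes or adjusted over the list alone, and the median on WT 4, at 0.54, was above all 4 KO medians. The list passed in 19 of 22 alternatives (adjusted p from 1.06e-06 to 0.225). Its call was also lost without WT 2 or KO 2 (adjusted p = 0.0566 and 0.225). The list median was 0.11 without WT 2, 0.14 without WT 3 and 0.36 without WT 4, and with median centring it was -0.00367 with a camera adjusted p of 6.30e-04 for a rise relative to the other genes.

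**Figure D2:**
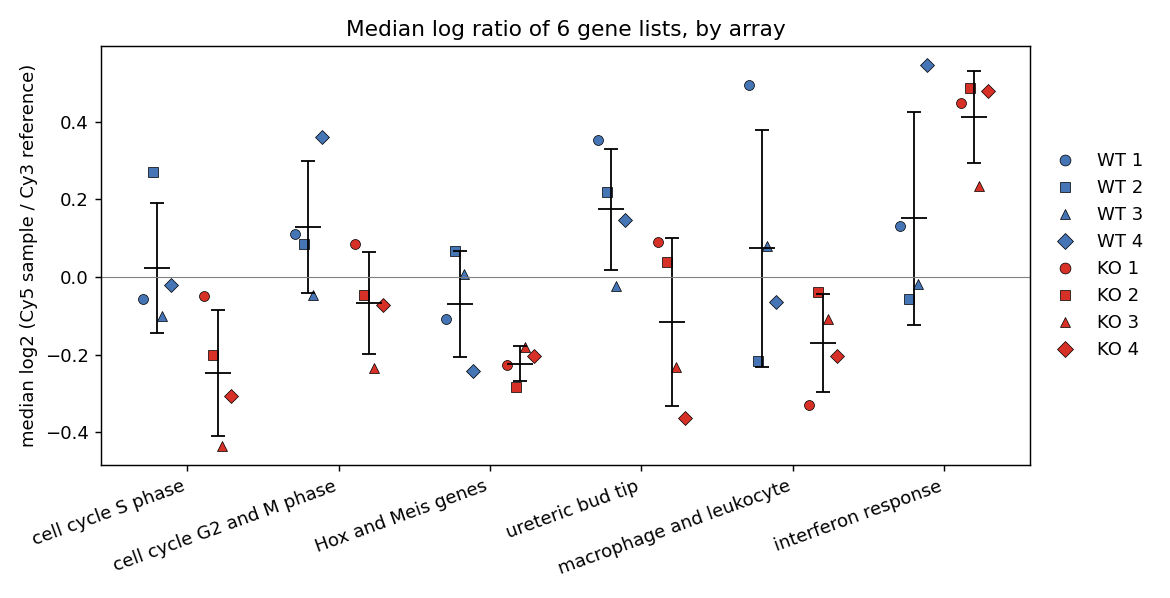
Median log2 ratio of Cy5 sample to Cy3 reference over the members of each shifted list, by array, with the mean and SD of each group of 4 as bars; colours mark WT and KO and symbols the replicate number. The S phase medians lie between -0.10 and 0.27 on the WT arrays and between -0.43 and -0.05 on the KO arrays.

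Other regulatory lists did not shift. Among cyclin-dependent kinase inhibitors and p53 targets (median -0.02; camera adjusted p = 0.987), Cdkn2b had a log2 fold change of 0.93 ± 0.22 (SE; 0.45 at its other tested probe) and Pmaip1 0.57 ± 0.14, and Cdkn1c had -0.53 ± 0.16. Cdkn2a, not well above background on any WT array, had 0.46 ± 0.11 (limma adjusted p = 0.112), a fitted value that depends on the background correction and is no bound. In this list 4 members were higher and 4 lower when adjusted over the list alone. Wnt targets had a median of 0.01 (camera adjusted p = 0.987), with Sp5 2.82-fold higher and Ascl2 at 0.76 ± 0.19 as the 2 members higher when adjusted over the list alone. The Notch list (median -0.03, with Hes1 at -0.50 ± 0.14) and the epithelial-mesenchymal transition list (median -0.09, with Edn1 at 0.71 ± 0.13) both had camera adjusted p = 0.987, and without KO 2 their medians were -0.10 and -0.20. The renin-angiotensin list, with Ace at -0.79 ± 0.21, had a median of -0.14 and camera adjusted p = 0.860.

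Secretory pathway genes of the unfolded protein response moved both ways, with a median of 0.06 (camera adjusted p = 0.939). That median was -0.04 without KO 1 and -0.48 with median centring. Xbp1 had a log2 fold change of 0.50 ± 0.09 (SE), or -0.12 with median centring, whereas the endoplasmic reticulum genes Manf, Pdia4 and Sdf2l1 had -0.49 ± 0.11, -0.41 ± 0.09 and -0.69 ± 0.16. Adjusted over the list alone, 2 members were higher and 4 lower. The cholesterol synthesis list (median 0.09; camera adjusted p = 0.285) and the immediate early and heat shock list (median -0.06; camera adjusted p = 0.860) held no member past either adjustment. The immediate early and heat shock median was 0.05 without WT 2 and -0.00147 without KO 2. The partners of Dot1l had a median of -0.02 (camera adjusted p = 0.537). Ell, at 0.45 ± 0.11, and Mllt10, at -0.46 ± 0.12, did not overlap between KO and WT arrays (limma adjusted p = 0.112 for both). They were the only such genes of 13 measured members, and 11.8% of all 23343 genes tested did not overlap either.

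Among the markers of other cells that the sort could hold, macrophage and leukocyte genes were lower in KO as a list, with 15 of 18 below 0 and a median of -0.25 (camera adjusted p = 0.0414), a call lost with an estimated correlation (adjusted p = 0.992) and kept in 7 of 22 alternatives (adjusted p from 0.00252 to 0.515). By array the list medians overlapped, with WT 2 at -0.22 and KO 2 at -0.04. S100a8 and S100a9, abundant in neutrophils, had log2 fold changes of -1.45 ± 0.31 and -1.20 ± 0.32 (SE), the lysozyme gene Lyz2 -0.39 ± 0.08 and the leukocyte actin-binding gene Coro1a -0.56 ± 0.12. No member passed over all genes and 4 were lower when adjusted over the list alone. The call was also lost without WT 1, where the median was -0.07 (adjusted p = 0.515), WT 3, KO 1, KO 2 or KO 4 (adjusted p = 0.0515, 0.122, 0.0867 and 0.0584), with medians of -0.15 without KO 1 and -0.39 without KO 2.

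None of the other cell type lists shifted. Medians were -0.33 for stroma and smooth muscle (camera adjusted p = 0.231), -0.29 for nephron progenitors (0.413), -0.26 for the proximal tubule (0.860), -0.16 for podocytes (0.987) and -0.14 for neural crest and neurons (0.521). They were -0.01 for the loop of Henle and distal tubule (0.703), 0.08 for erythroid genes (0.199) and 0.11 for the endothelium (0.521). Medians differed between arrays of 1 group: the proximal tubule list ranged from -0.30 to 1.07 over the WT arrays and from -1.32 to 0.58 over the KO arrays, and the endothelial list was at 0.98 on WT 4 against -0.32 to -0.04 on the other WT arrays. The proximal tubule median was 0.16 without KO 1, 0.02 without WT 1 and -0.47 without KO 3, the median without KO 2 was -0.59 for stroma, -0.50 for nephron progenitors, -0.15 for the proximal tubule, -0.07 for neural crest and neurons and 0.02 for the endothelium, and the endothelial median -0.05 without WT 1 or WT 2. The erythroid median was 0.16 without KO 2, 0.14 without KO 3 and -0.00527 without WT 2, and the stroma median -0.20 without KO 3. Of 17 listed erythroid genes 7 were measured, with a mean log2 fold change of 0.29. Their median of 0.08 is the value of Hbb-bh1, which was not well above background on any WT array. Without WT 4 the endothelial list had a median of 0.45 (camera adjusted p = 2.00e-06). WT 3 carried its own RNA in both dyes, with medians of 0.07 for stroma, -0.02 for the loop of Henle and 0.07 for intercalated cells. Without WT 3 the stroma list, at -0.51, the loop of Henle list, at 0.21, and the intercalated cell list, at 0.28, passed (camera adjusted p = 0.00602, 0.00602 and 1.89e-04). Without WT 1 the urothelium list, at 0.49, and the cholesterol list, at 0.12, did (camera adjusted p = 0.0108 and 0.0281). Among the sex-linked genes, Xist had 0.67 ± 0.39 (SE), Eif2s3y 0.47 ± 0.28, Ddx3y 0.21 ± 0.26 and Uty -0.02 ± 0.12 as log2 fold changes, and no member passed. Xist was at 1.37 on KO 1, and its log2 fold change was 0.29 without that array. Eif2s3y was at 1.56 on KO 4 and had a log2 fold change of 0.19 without it.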

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

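The tests of explanations in this part were chosen after the results were seen. The comparison with other splits of the arrays was planned. Chance marks about 1 in 20 groups of values as having an outlier by Dixon's criterion, which was applied to 9 groups of array measures, 54 of list medians and 228 of log ratios.

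KO 2 stood with the WT arrays on the first principal component, and 4947 genes were called without it against 2 with it. On genes called without KO 2 and 1 WT array at a time, KO 2 lay outside the other WT arrays on the KO side in 40.7% to 46.2%. The left-out WT array did so in 26.8% to 39.6%. The lowest of the 4 ratios was 1.08, with WT 3 left out, and the others were 1.29 to 1.52. KO 2 lay past the midpoint of the group means in 10.1% to 15.1% against 2.58% to 11.4% (lowest share of KO 2 over the highest of a WT array 0.888). The share of 11.4% was that of WT 3, the reference RNA, where KO 2 had 12.2%, and the other WT arrays had 2.58% to 8.73%. KO 2 exceeded the left-out WT array in all 4 comparisons, but by little against WT 3. This leaves a WT sample with a wrong label open. Single genes side with a KO sample, though most were noted in a comparison that included KO 2: 1190007I07Rik was at -1.28 on KO 2 and at -0.09 to -0.05 on the WT arrays, Aldh1a1 at 2.17 against at most 0.33, and Hoxb9 at -1.21 against at least -0.10. Signal of single probes may contribute to the calls without KO 2, since other probes of the genes called at least 2-fold showed 13.2% of the change in the median and are dimmer by construction, whereas the median log2 fold change of 0.51 of nuclear-retained long RNAs decides nothing on nuclear RNA, because the list was written after Neat1 and Malat1 were seen. A biological difference between the KO samples was not tested and stays open.

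1190007I07Rik lies on chromosome 10, as Dot1l does, with 52 measured genes between them, and 0.701% of the 15112 placed genes lie as near to Dot1l. A candidate explanation is sequence carried along with the targeted allele. Of the 20 measured neighbours of Dot1l, 4 had KO and WT arrays that did not overlap, and 21.6% of equal windows across the genome held as large a share. This leaves the explanation open, because a variant under 1 probe would not move the neighbours. An effect of the deletion on this gene is the biological alternative and was not tested separately.

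KO 3 stood apart as an array. Its median Cy5 signal was 636 against 122 to 137 on the other KO arrays, 7665 of its spots were marked as non-uniform or outlying, and its median Cy3 signal was 102 against 29 to 35. The Cy3 channel held the same reference RNA on every array. Spearman correlations of Cy3 signal with KO 3 were 0.717 to 0.804, against 0.920 to 0.937 among the other 7 arrays. The reference was thus read less alike on KO 3, and how far it cancels there was not tested. The gap of the KO 3 Cy3 median to the next array was 11.2 times the range of the other 7. This argues against the KO 3 RNA as the cause and is consistent with a difference in labelling, hybridisation or washing of that array. No biological explanation was tested.

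Among the list medians, 1 group of 54 had an outlier: the interferon response list on KO 3, at 0.23 against 0.45 to 0.49 on the other KO arrays. Among the log ratios of the named genes, 14 of 228 groups had one, 2 of them on KO 2. These were Mllt1 at -0.51 and Mvd at 0.86 on KO 2, Notum at 0.34 on KO 3, Ttc36 at -0.998 on KO 1 and Eif2s3y at 1.56 on KO 4. On the WT arrays they were Kit at 0.18, Krt5 at 0.39, Cdkn1c at 0.38, Slc12a1 at -0.0620 and Ddx3y at 0.11 on WT 3, Mcm2 at 0.58, Hes1 at -0.0205 and Junb at 1.12 on WT 2, and Itga5 at 1.91 on WT 4. WT 3 was hybridised with its own RNA, so its log ratios were held small by design (SD 0.275, the lowest of all arrays). For Krt5, Cdkn1c, Slc12a1 and Ddx3y the other WT arrays shared a larger difference from that RNA. For Kit their difference was smaller than on WT 3.

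All 35 splits of the 8 arrays into 4 and 4 were fitted. As many as 2 genes were called in 2 splits, the real one included, and the highest of the other splits, WT 1, WT 2, WT 4 and KO 2 against the rest, gave 2. As many as 1 gene of at least 2-fold was called in 2 splits, with 1 as the highest of the others. As many as 6 lists shifted in 32 splits, and another split shifted 16. Chance is excluded for none of these 3 counts.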

How the results depend on the processing

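The setting without KO 2 and KO 3 together was chosen after the data were seen, and all others were planned. The count of 2 genes was 1 with a normexp offset of 0, no background subtraction or the mean over probes, 0 in limma with median centring or Cy5 alone (6785 and 3751 at an unadjusted p under 0.05), 5 with scaling between arrays, 4 without a filter, 16 with a trend and robust eBayes, 4542 with array weights and 5510 without KO 2 and KO 3. With single arrays left out it ranged from 1 to 4947, the highest without KO 2. The count of 1 gene of at least 2-fold was 3 with the scanner log ratio or the series table, 0 with median centring or Cy5 alone, 2 with scaling, 7 with a trend, 587 with array weights, 876 without KO 2 and KO 3, and 1 to 650 with single arrays left out. The share of calls that were higher in KO was 33.3% with the scanner log ratio or the series table, 50% with a trend, 52.6% with array weights, 47.2% without KO 2, 62.5% without KO 3, 57.2% without both and 66.7% without WT 3, against 0 of the 2 genes. The array weights were 0.338 for KO 2 and 0.453 for KO 3, the lowest of the 8. Dot1l had a log2 fold change of -0.18 with median centring (adjusted p = 0.615) and 0.34 without KO 2 and KO 3 (adjusted p = 0.0299), and 0.11 to 0.24 with single arrays left out. The 6 shifted lists became 3 with the scanner log ratio, the series table or a filter on all 8 arrays, 1 without KO 2 and KO 3, and 0 with an estimated correlation (smallest adjusted p = 0.992) or fry (smallest adjusted p = 0.360), and 1 to 7 with single arrays left out. The interferon median was -0.00367 with median centring, where the median of all genes was -0.30 and camera still called a rise, and the loop of Henle list went from -0.01 to 0.21 without WT 3, where it passed; over single arrays left out it ranged from -0.0242 to 0.214. The cause of the other changes was not tested.

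Outside the single left-out arrays, 1424 of 1576 values of named genes and 315 of 378 list medians kept their direction and side of the threshold, 11 and 25 lost the call, 121 and 2 gained one, and 20 and 35 changed sign without a call. All 20 sign changes of genes came with median centring or Cy5 alone, which moved the median of all genes to -0.30 and -0.17. With single arrays left out, 25 of 216 list medians changed sign without a call. Deviations of same-numbered KO and WT arrays correlated at -0.24, 0.05, 0.11 and -0.02, and only number 3 correlated best with its own. This gives no sign that the numbers pair the samples, but so few correlations cannot exclude it. With the replicate block limma called 0 genes (5264 at an unadjusted p under 0.05), 0 by at least 2-fold, and 5 lists shifted, where 1190007I07Rik had an adjusted p of 0.0947, Gadd45gip1 of 0.134 and the macrophage list of 0.0745. Signal over background limits what was tested: Cy5 was well above background on 52.4% to 56.2% of spots on the WT arrays.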

Other observations

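The genes and the test in this part were chosen after their values were seen. Beyond the lists, several genes whose KO and WT arrays did not overlap just missed the threshold. Aldh1a1, which makes retinoic acid, had a log2 fold change of 1.69 ± 0.21 (SE; limma adjusted p = 0.0677), with 2.17 on KO 2 and at most 0.33 on a WT array. The water channel gene Aqp5 had 1.23 ± 0.17 (adjusted p = 0.0804; 0.53 at its other tested probe), and Scel, which encodes a protein of the epithelial cell envelope, 0.84 ± 0.11 (adjusted p = 0.0834). Angpt2, an angiopoietin, had 0.72 ± 0.11 (adjusted p = 0.0834). The tight junction gene Cldn6 had -0.87 ± 0.09 (adjusted p = 0.0570) and Cuedc1 -1.16 ± 0.15 (adjusted p = 0.0677). These 6 genes were taken from those whose measured KO arrays all lay on the same side of all WT arrays. That separation, KO 2 included, is therefore how they were chosen and not a result. Cldn6 and Scel had no value on KO 3.

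Without KO 2, Neat1 had a log2 fold change of 2.46 ± 0.31 (SE; limma adjusted p = 0.00241) and Malat1 of 1.71 ± 0.19 (adjusted p = 0.00166), where KO 2 differed from the WT mean by 0.39 and -0.19. Of 11 measured nuclear-retained long RNAs, 6 were higher, 1, Tug1, was lower at -0.58, and Peg13, Ftx, Pvt1 and Dleu2 did not pass. On KO 2 itself Meg3 lay 0.82 and Mirg 0.84 above the WT mean, whereas the median of the 11 lay -0.12 from it. Of 45 measured histone genes, 26 were lower without KO 2 and 0 higher, against 2612 lower and 2335 higher of all 23343. Their median was -0.58 without KO 2 and -0.52 with all arrays, and the median on KO 2 lay -0.31 from the WT mean. H4c3 had -1.48 ± 0.22 (adjusted p = 0.00374) and H1f1 -1.37 ± 0.17 (adjusted p = 0.00221). Rmrp, the RNA of a ribonucleoprotein that processes other RNAs, had -1.85 ± 0.20 (adjusted p = 0.00122). Other large differences without KO 2 were Slc10a1 at 2.52, Elk1 at 2.52, Igf2 at -1.39 and Lepr at -1.36. On KO 2 itself they differed from the WT mean by -0.04, -0.12, -0.13 and -0.06. Slc10a1 and Elk1 ran nearly alike, at 2.70 and 2.45 on KO 1 and at 2.49 and 2.31 on KO 3. Kctd14, Glrx2, Ndor1, Med16 and Ttc38, also among the largest rises without KO 2, lay close to them. They were at 2.28 to 2.54 on KO 1 and at 2.08 to 2.36 on KO 3. Why these probes share a profile was not tested, so their values cannot be read as separate changes of each gene. Other probes of genes called at least 2-fold without KO 2 showed 13.2% of the change in the median. Signal of single probes is therefore not excluded for these genes.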
